A study of Drosophila melanogaster with 12 samples.

How the data were processed

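RNA abundance was measured on 12 custom Agilent arrays of 2 colours, each holding 105072 spots. Wild-type Oregon R fly embryos of 6 stages were compared with a common reference, RNA of mixed embryos from 0-16 h of development. Per the labels, each stage had 2 biological repeats, the stage RNA carried Cy5 and the reference RNA carried Cy3 on every array. A dye effect that is constant across arrays therefore cancels in a difference between stages. RNA was prepared with TriZol and an RNeasy clean-up and labelled with the Agilent QuickAmp kit, per the labels' protocols. One label field calls the molecule total RNA and the protocol calls it polyA RNA.

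Per the file headers, the deposited scanner files were written by Agilent Feature Extraction 9.5.3.1 and hold intensity values on a linear scale for each spot and channel. The columns used were the spot mean and the local background median, both unprocessed, the processed signal, and the flags per spot. The processed signal is background-subtracted and dye-normalized by Feature Extraction, per the file headers. The deposited series table holds 1 column per array from the authors, and the submitters' processing notes name limma without settings. Across probes each column followed the processed Cy5 intensity of its array most closely, with r from 0.950 to 0.970, against 0.124 to 0.300 for the log ratio. The authors' table was therefore read as a normalized Cy5 intensity on a linear scale with a floor of 0, and its method and scaling stay unknown. The medians of its columns, from 0-1 h to 19-22 h with repeat 1 before repeat 2, were 2.42, 4.54, 6.30, 4.54, 5.90, 4.13, 5.54, 6.26, 5.96, 6.56, 4.99 and 6.47.

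Analysis used R 4.3.3 with limma 3.58.1 and Python 3.11.15. Background was corrected with limma's normexp with an offset of 50. Log2 ratios of Cy5 over Cy3 were normalized by loess within each array on spots that were neither controls nor outliers, with no scaling between arrays. Control spots were left out after background correction, and values with an outlier flag of the spot itself were left out. Values whose local background was marked as uneven and exceeded the spot were left out too, 0 to 66 per array, which was also decided after the data were examined. The parameters of normexp were fitted on spots without any outlier flag, which is a change made after the data were examined. With all spots in that fit, bright specks in the local background of up to 20 spots gave fitted background means down to -382 on the affected arrays, against -8.29 to -11.1 for Cy5 without them. The fit on all spots was kept as an alternative.

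Spots of one probe were averaged. Of 83472 distinct probes that were not controls, 23447 were catalogue gene probes and 60025 were contig probes without coordinates. Through its accession or the name in the file, 20465 catalogue probes matched a single gene of the Release 6 reference table, which was used for names alone. Another 2543 catalogue probes kept the name of the file. Of the rest, 277 without a gene name and 162 matching several genes were not used. A catalogue probe was kept when its Cy5 signal was well above background on both arrays of at least 1 stage, which left 18276 probes. A gene was the mean of its kept probes, leaving out a probe with an outlier on any array where another was kept. This gave 12199 genes. Coordinates are those of the probes in the scanner files, on build dm3. The 3 list members nos, Dl and phm had no match and are not analysed here.

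Between 13035 and 18717 catalogue probes per array were well above background in Cy5, and between 16230 and 16986 in Cy3. The number of arrays limits the precision. The lowest correlation between log ratios of any pair of arrays was -0.28 over all 83472 probes and -0.36 over the kept catalogue probes, for 19-22 h repeat 2 and cycle 13-early 14 repeat 1. The direction was kept as the labels state the dyes and stages far apart could oppose each other around a mixed reference.

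All 12 arrays were fitted together with limma (lmFit and eBayes) and 1 mean per stage, which left 6 residual degrees of freedom and 3.86 from the prior. The 6 comparisons were the 5 steps between neighbouring stages and 4-5 h against 0-1 h. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and the count at 2-fold or more is given beside it. A moderated F test covered any difference among the stages. Values are log2 ratios to the reference, given as mean ± SD with n = 2 arrays per stage. Where a gene was not well above background on any array of a stage, the fold is a lower bound from the Cy5 channel alone after loess and Aquantile, which is open to dye bias as the dyes were not swapped. Scanner files give slides and scan dates. Both repeats of 3-4 h shared 1 slide and both repeats of 4-5 h another, while repeats of the other stages lay on different slides and scan dates.

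The 31 gene lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The lists covered maternal localized and egg activation genes, germ plasm and piRNA, cellularization, sex determination and X counting, gap and terminal, pair-rule, segment polarity and Hox genes. Further lists held dorsal ectoderm and amnioserosa, neuroectoderm and midline, mesoderm and gastrulation, endoderm and gut primordium, neurogenic and neuroblast, glia, neuron function, muscle and cuticle genes. The remaining lists were chitin and trachea, gut digestion, hemocyte, fat body and larval serum, ovary follicle and yolk, testis and male, ribosomal protein, ATP synthase and cytochrome c oxidase, and cell cycle and checkpoint. The last were zygotic activators and decay, dosage compensation, ecdysone pathway, heat shock and stress, and antimicrobial peptide. Some lists share genes, at most 4 tested members each. Lists with at least 5 tested members were tested with camera at an inter-gene correlation of 0.01, two-sided, adjusted over 180 pairs of list and comparison. Camera with an estimated correlation stands beside it. For each comparison the rule named, among matched genes well above background on both arrays of a stage and at an adjusted p under 0.05, the 5 largest rises and falls with no overlap between repeats, the 3 most changed members of the 5 lists with the smallest camera p, and a fixed set of reference points.

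The fit was tested on simulated data for each comparison with 12185 genes and 50 changed genes per size. A true log2 difference of 1 was called for 40 of 50 genes in cycle 13-early 14 against 0-1 h, 39 in the step to mid-late cycle 14, 41 in the step to 3-4 h, 38 in the step to 4-5 h, 43 in the step to 19-22 h and 42 in 4-5 h against 0-1 h. A difference of 0.5 was called for 6 to 13 of 50. The simulated noise was independent between arrays with a single spread per gene over all stages, and few genes were changed. The real arrays differ in all these respects, so these counts are not detection rates for the data.

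Alternatives changed the background correction, the within-array and between-array normalization, the channel, the probe filter, the summary per gene, the outlier handling, the empirical Bayes setting, the blocks for slide, scan date and repeat, the arrays in the fit and the threshold, and used the authors' table. Each array was also left out in turn. Of these, the scan date as a block, the second scan date alone, loess on catalogue probes alone and normexp fitted on all spots were added after the data were examined.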

Results

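RNA abundance was measured in wild-type Oregon R fly embryos at 6 stages, staged by hand at room temperature, with 100 to 150 embryos per collection. The stages were 0-1 h, cycle 13-early 14, mid-late cycle 14, 3-4 h, 4-5 h and 19-22 h, with 2 biological repeats and 2 arrays each. Some label fields name the stages differently: the titles' cycle 13-early 14 is also given as cycle 12-13, mid-late cycle 14 as cycle 14-15, and the 19-22 h repeats as 21-22 h and 20-22 h. Every value is the log2 ratio of a stage to a mixed 0-16 h reference, so a fall can mean less RNA of a gene per unit of labelled RNA at that stage. The catalogue probes well above background in Cy5 numbered 13035 to 18717 per array. The median Cy5 signal of catalogue probes was 350 on the array of 19-22 h repeat 1 and lay between 81.5 and 167 on the other 11 arrays. Across kept probes the repeats of a stage correlated with r = 0.980 at 0-1 h, 0.967 at cycle 13-early 14, 0.972 at mid-late cycle 14, 0.990 at 3-4 h, 0.996 at 4-5 h and 0.960 at 19-22 h, where probes are not independent replicates.

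Over the 6 stages, 11005 of 12199 genes (90.2%) differed by the F test. Of these, 3523 genes (32.0%) had their highest mean at 19-22 h and 2902 (26.4%) at 0-1 h. Cycle 13-early 14 held the highest mean of 1447 genes, mid-late cycle 14 of 1254, 3-4 h of 733 and 4-5 h of 1136. Maternal RNAs of bcd and osk were high at 0-1 h, Kr stayed high from cycle 13-early 14 to 4-5 h and twi to 3-4 h, and the Mhc mean was above that of the reference at 19-22 h alone. A list count is followed by the count adjusted over the list alone where that differed. Of 180 pairs of list and comparison, 78 passed camera at the preset correlation, and 0 of them passed with an estimated correlation, where the lowest adjusted p was 0.277. The median log ratio of kept probes shifted by -0.11 from 0-1 h to cycle 13-early 14, by -0.12 from 4-5 h to 19-22 h and by -0.13 from 0-1 h to 4-5 h. Without loess these shifts were -0.53, 0.20 and -0.68, the steps to 3-4 h and 4-5 h shifted by -0.27 and 0.12, and Agilent's processed signals gave -0.21 for the step to 19-22 h.

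**Figure D1:**
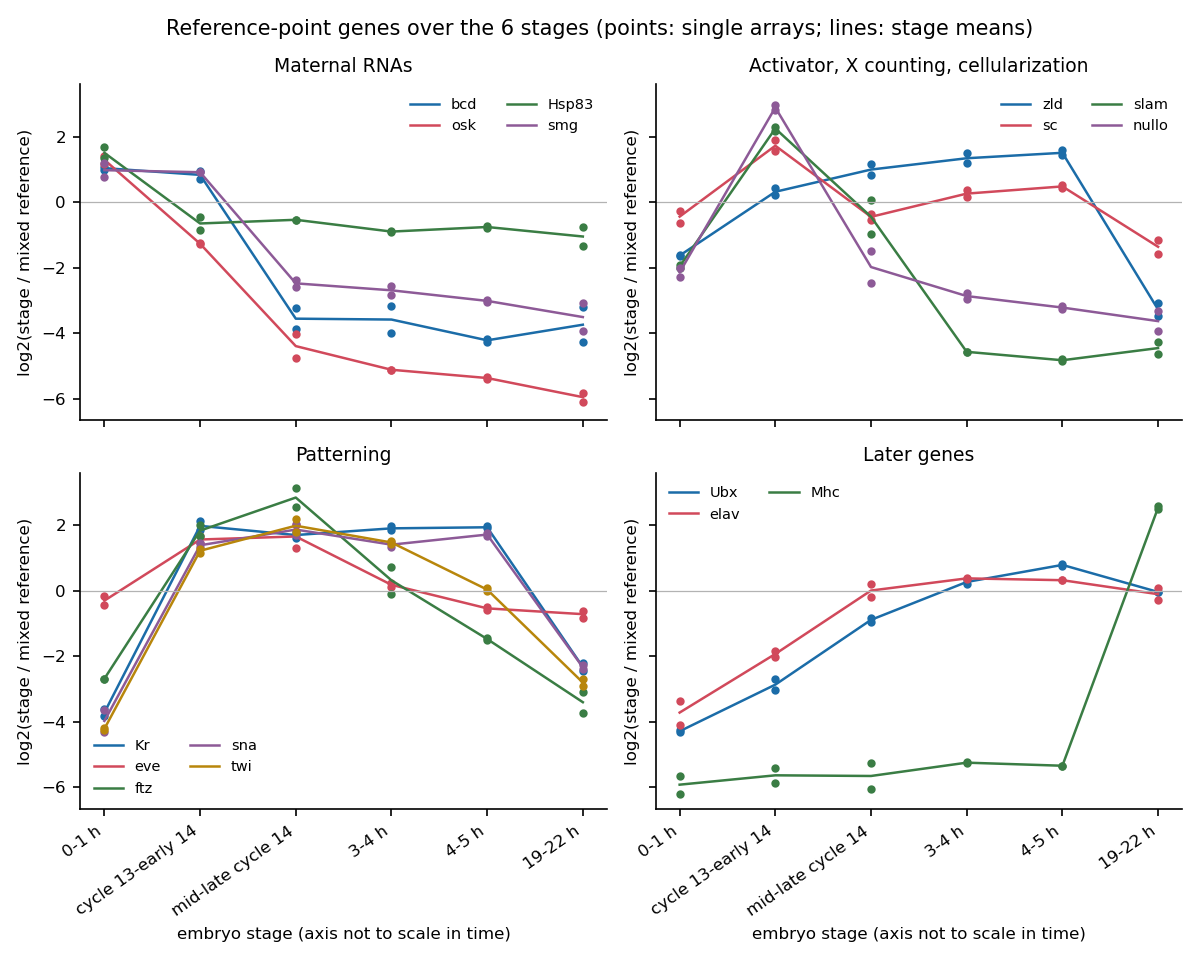
Log2 ratio to the mixed reference (vertical axis) of 16 reference-point genes at the 6 stages (horizontal axis), with a point per array and a line through the stage means. The bcd mean was 0.84 at cycle 13-early 14 and -3.56 at mid-late cycle 14, and the Mhc mean was -5.35 at 4-5 h and 2.54 at 19-22 h.

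The step from 0-1 h to cycle 13-early 14 asks which RNAs appear and which disappear before and during the onset of zygotic transcription. The largest rise was that of SNCF, 349-fold, from a log2 ratio of -5.62 ± 0.15 to 2.82 ± 0.26 (SD, n = 2 per stage, adjusted p = 2.9e-08, probe on chromosome 3L from 13372208 to 13372267). Z600, an inhibitor of mitosis at cycle 14, rose 265-fold, bard 257-fold, halo, which acts in lipid droplet transport, 181-fold, and Sry-alpha, which acts in cellularization, 157-fold. The largest fall was that of dhd, a maternal thioredoxin, by 6.53 on the log2 scale, from 1.25 ± 0.30 to -5.28 ± 0.03 (adjusted p = 6.39e-08, probe on chromosome X from 5207090 to 5207149).

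Of 12 gap and terminal genes 11 rose and 1 fell (camera adjusted p = 5.92e-09, adjusted p = 0.277 with an estimated correlation). Kr rose 52.2-fold, hkb 55.0-fold and tll 44.9-fold, and hkb was well above background on 1 of 2 arrays at 0-1 h. Of 11 pair-rule genes 10 rose and 0 fell (camera adjusted p = 7.28e-09, adjusted p = 0.277 with an estimated correlation), among them hry, odd and opa by 5.69, 5.00 and 5.27 on the log2 scale. Of 17 genes of the dorsal ectoderm and amnioserosa 15 rose and 1 fell (camera adjusted p = 2.16e-09, adjusted p = 0.277 with an estimated correlation), with scw up 56.1-fold and Doc1 up 27.0-fold, and Doc1 was well above background on 1 of 2 arrays at 0-1 h. The mesoderm regulators twi and sna rose by 5.44 and 5.37, while their list was not called, with 9 of 19 members that rose and 7 that fell (camera adjusted p = 0.167). Of 11 cellularization genes 10 rose and 0 fell (camera adjusted p = 6.23e-07, adjusted p = 0.277 with an estimated correlation), including slam by 4.21 and nullo by 5.04. Of 10 genes of sex determination and X counting 8 rose, 9 adjusted over the list alone, and 1 fell (camera adjusted p = 6.83e-05, adjusted p = 0.277 with an estimated correlation), and sc rose 4.49-fold. The zygotic activator zld rose 3.86-fold, eve 3.65-fold with 1 of 2 arrays above background at 0-1 h, and Ubx at least 2.62-fold.

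In the neurogenic and neuroblast list 15 of 26 rose and 1 fell (camera adjusted p = 3.87e-06, adjusted p = 0.434 with an estimated correlation). In the neuroectoderm and midline list 7 of 13 rose and 0 fell (camera adjusted p = 0.00017, adjusted p = 0.359 with an estimated correlation). Of 16 segment polarity genes 9 rose (camera adjusted p = 0.00383, adjusted p = 0.434 with an estimated correlation) and of 7 endoderm genes 4 rose and 1 fell (camera adjusted p = 0.00607, adjusted p = 0.322 with an estimated correlation), calls that loess on catalogue probes alone ended at 0.0553 and 0.0653. Of 7 dosage compensation genes 4 rose, 5 adjusted over the list alone (camera adjusted p = 0.0126, adjusted p = 0.277 with an estimated correlation). Of 92 ribosomal protein genes 71 rose, 81 adjusted over the list alone, and 0 fell (camera adjusted p = 1.7e-13, adjusted p = 0.434 with an estimated correlation). Their median difference of 0.71 kept its sign under 7 other scalings, and with loess on catalogue probes alone it was 0.11 and the call ended at 0.0781. The ATP synthase and cytochrome c oxidase list rose in 17 of 28 members and fell in 1 (camera adjusted p = 0.00246, adjusted p = 0.577 with an estimated correlation), a call lost under 5 other scalings.

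Of 34 maternal localized and egg activation genes 21 fell and 3 rose (camera adjusted p = 2.28e-05, adjusted p = 0.343 with an estimated correlation). Of them osk, needed for the pole plasm, fell by 2.56 on the log2 scale and Hsp83, a chaperone, fell by 2.16, while bcd (-0.21, adjusted p = 0.711) did not pass the test. The translational repressor smg did not pass either (-0.06, adjusted p = 0.882). Of 19 germ plasm and piRNA genes 12 fell and 2 rose (camera adjusted p = 0.0213, adjusted p = 0.617 with an estimated correlation), and 4 other scalings ended that call. Further falls were those of Gapdh2, a glycolytic enzyme (-5.50), CG31075 (-5.44), yin, an oligopeptide transporter (-5.34), and CG14545 (-5.30).

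In all 5212 genes changed in this step, 2377 higher and 2835 lower at cycle 13-early 14, and 2291 of them by 2-fold or more, of which 1780 were lower. Both stages shared slides, and with the slide as a block 6257 genes passed, 5211 of them among the 5212, while 6174 passed with the scan date as a block. The differences on the 2 slides correlated with r = 0.977 across genes, which are not independent replicates. On those slides, which were scanned on different dates, the 14 called lists kept their direction, and Kr differed by 5.68 and 5.73, SNCF by 8.37 and 8.52, and dhd by -6.29 and -6.77. The lists, SNCF and dhd were picked on these same arrays, so an equal direction was likely in advance and is no independent check. The share of changed genes that were higher was 45.6%, against 62.6% in the authors' table and 24.6% without loess.

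The step from cycle 13-early 14 to mid-late cycle 14 covers the time when the blastoderm is divided into cells and maternal RNA is cleared. The maternal RNA of bcd fell by 4.40 on the log2 scale, from 0.84 ± 0.16 to -3.56 ± 0.46 (SD, n = 2 per stage, adjusted p = 6.16e-06, probes on chromosome 3R from 2581624 to 2582493). The early zygotic gene nullo fell by 4.88 after its earlier rise, from 2.89 ± 0.11 to -1.98 ± 0.69. Among matched genes the largest rises were those of ImpL2, which binds insulin-like peptides, 15.0-fold, CG32982 13.2-fold, pnr, a GATA factor, 11.2-fold, and the Notch target E(spl)m5-HLH 9.63-fold.

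Of 34 maternal localized and egg activation genes 28 fell and 0 rose (camera adjusted p = 1.78e-11, adjusted p = 0.277 with an estimated correlation). Among these, swa, which localizes bcd RNA, fell by 4.17, twe, a Cdc25 phosphatase, fell by 3.83 and osk fell by 3.13. The list of zygotic activators and decay genes held 9 members that fell, 10 adjusted over the list alone, and 1 that rose (camera adjusted p = 0.0039, adjusted p = 0.277 with an estimated correlation), and smg fell by 3.40 on the log2 scale. Of 19 germ plasm and piRNA genes 11 fell, 12 adjusted over the list alone, and 3 rose (camera adjusted p = 0.013, adjusted p = 0.577 with an estimated correlation). CG9917 (-4.40), CG5455 (-4.35) and Gdap2 (-4.34) fell as well.

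Of 19 mesoderm and gastrulation genes 14 rose, 15 adjusted over the list alone, and 1 fell (camera adjusted p = 4.91e-06, adjusted p = 0.343 with an estimated correlation). Within this list stumps, which acts in FGF signalling, rose 9.46-fold, tin, a regulator of heart mesoderm, 8.70-fold, and the FGF receptor htl 7.57-fold. Of 11 pair-rule genes 10 rose and 0 fell (camera adjusted p = 9.53e-05, adjusted p = 0.343 with an estimated correlation), with opa, sob and drm up by 2.04, 2.11 and 1.71. In the neuroectoderm and midline list 9 of 13 rose, 10 adjusted over the list alone (camera adjusted p = 0.000111, adjusted p = 0.343 with an estimated correlation), with ths, an FGF ligand, up 4.73-fold, ind 4.45-fold and sim 3.00-fold. Of 26 neurogenic genes 17 rose and 1 fell (camera adjusted p = 0.000132, adjusted p = 0.54 with an estimated correlation). Of 8 Hox genes 6 rose (camera adjusted p = 0.000308, adjusted p = 0.277 with an estimated correlation), Ubx by 1.98. Of 16 segment polarity genes 9 rose and 1 fell (camera adjusted p = 0.00203, adjusted p = 0.406 with an estimated correlation). In the dorsal ectoderm list 10 of 17 rose and 3 fell, 4 adjusted over the list alone (camera adjusted p = 0.0126, adjusted p = 0.577 with an estimated correlation), and Agilent's processed signals ended that call at 0.0708. Other reference points were slam, which fell by 2.70, sc, which fell by 2.17, twi up by 0.76, elav up by 1.94, and Kr (-0.28, adjusted p = 0.159), eve (0.09, adjusted p = 0.774), sna (0.48, adjusted p = 0.0814) and Hsp83 (0.11, adjusted p = 0.718), which did not pass in the fit without blocks. Kr passed with the scan date as a block.

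Of 92 ribosomal protein genes 19 rose, 2 adjusted over the list alone (camera adjusted p = 1.8e-06, adjusted p = 0.617 with an estimated correlation), a call that ended under 4 other scalings with medians of 0.02 to 0.08. The ATP synthase and cytochrome c oxidase list had 2 members that rose, 1 adjusted over the list alone (camera adjusted p = 0.0409, adjusted p = 0.719 with an estimated correlation), and its call ended under 5 other scalings.

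In this step 4832 genes changed, 2333 higher and 2499 lower, and 2210 by 2-fold or more. With the scan date as a block 5893 genes passed, all 4832 among them, and 4629 passed with the slide as a random block. No slide held both stages. The bcd difference was -4.18 and -4.61 on the 2 dates, and the 12 called lists kept their direction on both. Those lists were called on these same arrays, so that was likely in advance. With background parameters fitted on all spots 3036 genes passed and without loess 784.

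The step from mid-late cycle 14 to 3-4 h follows embryos into gastrulation and germ band extension. E(spl)mgamma-HLH rose 43.1-fold, from -4.17 ± 0.31 to 1.25 ± 0.20 (SD, n = 2 per stage, adjusted p = 1.75e-06, probe on chromosome 3R from 21826323 to 21826382), E(spl)mdelta-HLH 27.0-fold and wor, a neuroblast transcription factor, 10.1-fold, with 1 of 2 arrays above background for wor at mid-late cycle 14. The largest falls were those of Elba1 (-4.44) and Elba3 (-3.95), which act in early insulator binding, slam (-4.13), Z600 (-4.07) and SNCF (-3.87).

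Of 26 neurogenic and neuroblast genes 18 rose, 19 adjusted over the list alone, and 1 fell (camera adjusted p = 2.16e-09, adjusted p = 0.343 with an estimated correlation). Of 16 segment polarity genes 10 rose and 0 fell (camera adjusted p = 4.62e-05, adjusted p = 0.322 with an estimated correlation), with en, inv and slp2 up by 1.86, 1.85 and 1.23. Of 8 Hox genes 7 rose (camera adjusted p = 0.00028, adjusted p = 0.277 with an estimated correlation), among them lab by 1.54, Ubx by 1.16 and Antp by 0.98. Of 12 gap and terminal genes 7 fell and 0 rose (camera adjusted p = 0.0011, adjusted p = 0.343 with an estimated correlation), and tll fell by 0.92. The pair-rule list had 6 of 11 members that fell and 2 that rose, 3 adjusted over the list alone (camera adjusted p = 0.0207, adjusted p = 0.577 with an estimated correlation), and Agilent's processed signals ended the call at 0.0919; ftz (-2.53) and eve (-1.48) fell. Of 34 maternal genes 9 fell, 10 adjusted over the list alone, and 2 rose (camera adjusted p = 0.00333, adjusted p = 0.513 with an estimated correlation), including Tl (-1.74), ea (-1.52) and tor (-1.51) of the dorsal and terminal pathways.

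Of 11 cellularization genes 6 fell and 1 rose (camera adjusted p = 0.0148, adjusted p = 0.299 with an estimated correlation). Of 19 germ plasm and piRNA genes 4 fell, 5 adjusted over the list alone, and 1 rose (camera adjusted p = 0.0207, adjusted p = 0.617 with an estimated correlation). Of 8 glia genes 3 rose (camera adjusted p = 0.0389, adjusted p = 0.343 with an estimated correlation). Of 30 cell cycle genes 10 rose, 11 adjusted over the list alone, and 2 fell, 3 adjusted over the list alone (camera adjusted p = 0.0178, adjusted p = 0.434 with an estimated correlation), and without loess their median was -0.34, where kept probes as a whole shifted by -0.27. Of 19 mesoderm genes 7 rose, 8 adjusted over the list alone, and 1 fell (camera adjusted p = 0.0418, adjusted p = 0.653 with an estimated correlation), with a median of -0.24 without loess, against that shift of -0.27. Of 15 chitin and trachea genes 5 rose (camera adjusted p = 0.0446, adjusted p = 0.617 with an estimated correlation), with a median of 0.28 that was -0.05 without loess and -0.01 on the second scan date alone. The calls of the cellularization and glia lists ended with loess on catalogue probes alone, and 5 other scalings ended that of the chitin and trachea list. Genes outside these lists rose as well, cv-c 9.35-fold and CG8745 8.54-fold.

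In this step 2986 genes changed, 1645 higher and 1341 lower, and 815 by 2-fold or more. With the scan date as a block 3975 genes passed, 2958 of them shared, and 2285 with the slide as a random block. Both 3-4 h arrays lay on a slide that held no other stage, so slide and stage cannot be told apart in this step. The count was 1500 without 3-4 h repeat 2, 1935 without 3-4 h repeat 1 and 1897 without mid-late cycle 14 repeat 1. It was 1472 with background parameters fitted on all spots, 1857 with Agilent's processed signals, 1503 with the authors' table and 115 without loess, and the share that was higher was 26.1% without loess, 69.0% with all spots and 72.9% in the authors' table, against 55.1%.

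The step from 3-4 h to 4-5 h compares neighbouring times of the extended germ band. Lip4, a lipase, rose 8.01-fold, from -2.47 ± 0.52 to 0.53 ± 0.03 (SD, n = 2 per stage, adjusted p = 0.000202, probe on chromosome 2L from 10531355 to 10531414). Tps1, of trehalose synthesis, rose 5.86-fold, and CG7763, axed and CG12011 rose 6.84-, 6.77- and 5.12-fold. SNCF fell by 3.85 on the log2 scale, and zen2, a paralog of zen (-3.25), bard (-2.85), CG42709 (-2.81) and CG5880 (-2.73) fell too.

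The neurogenic and neuroblast list rose further, 10 of 26 members, 13 adjusted over the list alone, with 0 that fell, 1 adjusted over the list alone (camera adjusted p = 3.05e-08, adjusted p = 0.343 with an estimated correlation). In it wor rose 4.06-fold, ase, a proneural gene of neuroblasts, 3.40-fold and E(spl)m3-HLH 3.12-fold. Of 8 glia genes 3 rose, 4 adjusted over the list alone (camera adjusted p = 0.00463, adjusted p = 0.277 with an estimated correlation), with moody, a receptor of glia at the blood-brain barrier, up 3.69-fold and gcm at 0.45 (adjusted p = 0.0624), which did not pass. Of 30 cell cycle genes 3 rose (camera adjusted p = 0.00284, adjusted p = 0.343 with an estimated correlation), a call lost without loess (0.106) and in the authors' table (0.0597). Of 11 pair-rule genes 5 fell, 6 adjusted over the list alone, and 0 rose, 1 adjusted over the list alone (camera adjusted p = 0.00326, adjusted p = 0.434 with an estimated correlation), including prd (-1.84), opa (-1.81) and ftz (-1.79). Of 34 maternal genes 4 fell, 5 adjusted over the list alone, and 3 rose (camera adjusted p = 0.0307, adjusted p = 0.617 with an estimated correlation), in which ea fell by 2.05 and Tl rose by 1.07. The mesoderm regulator twi fell by 1.44, and sna (0.31, adjusted p = 0.431), Kr (0.03, adjusted p = 0.944) and elav (-0.06, adjusted p = 0.939) did not pass.

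In this step 1436 genes changed, 697 higher and 739 lower, and 393 by 2-fold or more. Both arrays of each stage lay on a slide of their own and the 4 arrays shared a scan date, so slide and stage cannot be told apart here, and 667 genes passed with the slide as a random block and 2361 with the scan date as a block. The count was 470 without 3-4 h repeat 1, 893 without 3-4 h repeat 2, 523 without 4-5 h repeat 1 and 543 without 4-5 h repeat 2. It was 139 with background parameters fitted on all spots, 803 with Agilent's processed signals, 536 with the authors' table and 16 without loess.

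The step from 4-5 h to 19-22 h spans organ formation to shortly before hatching. Lcp65Ag3, a larval cuticle protein, rose 1974-fold and Act57B, a muscle actin, 1827-fold, from -7.89 ± 0.06 to 2.94 ± 0.45 (SD, n = 2 per stage, adjusted p = 4.81e-08, probe on chromosome 2R from 16833823 to 16833882). The largest falls were those of CG4440 (-8.14 on the log2 scale), Tom (-8.06), BobA (-7.94), CG31253 (-7.47) and sala (-7.45), and Tom and BobA belong to the Bearded family of Notch antagonists.

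Of 95 cuticle genes 76 rose and 2 fell (camera adjusted p = 1.95e-10, adjusted p = 0.322 with an estimated correlation), Lcp65Ag2 1560-fold and Lcp65Ag1 1292-fold. CG7465, which no list holds, rose 1595-fold. Of 23 muscle genes 22 rose and 1 fell (camera adjusted p = 6.46e-08, adjusted p = 0.343 with an estimated correlation), TpnC47D 315-fold, Mlc1 259-fold and Mhc 237-fold. Of 28 gut digestion genes 27 rose and 1 fell (camera adjusted p = 3.32e-09, adjusted p = 0.317 with an estimated correlation), with the serine proteases Jon65Ai, Jon25Biii and Jon65Aiv up 335-, 319- and 267-fold. Of 24 neuron function genes 23 rose and 0 fell (camera adjusted p = 4.71e-07, adjusted p = 0.343 with an estimated correlation), with a median of 2.85, and elav (-0.43, adjusted p = 0.113) was not among them. Of 14 hemocyte genes 11 rose and 2 fell (camera adjusted p = 0.0151, adjusted p = 0.317 with an estimated correlation). Of 15 chitin and trachea genes 11 rose and 4 fell (camera adjusted p = 0.0479, adjusted p = 0.617 with an estimated correlation), and loess on catalogue probes alone ended the call at 0.0781. The ATP synthase and cytochrome c oxidase list rose in 20 of 28 members and fell in 6 (camera adjusted p = 0.033, adjusted p = 0.707 with an estimated correlation), and its call ended under 5 other scalings.

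Of 30 cell cycle genes 29 fell and 0 rose (camera adjusted p = 1.82e-09, adjusted p = 0.277 with an estimated correlation), including Cdk1 (-5.29), polo (-5.17) and Mcm5 (-5.05). Of 26 neurogenic and neuroblast genes 26 fell (camera adjusted p = 2.11e-08, adjusted p = 0.343 with an estimated correlation), including Brd (-6.89) and l(1)sc (-6.83). Of 19 mesoderm genes 16 fell and 1 rose (camera adjusted p = 0.000805, adjusted p = 0.434 with an estimated correlation), including twi (-2.84) and sna (-4.06). Of 17 dorsal ectoderm genes 13 fell (camera adjusted p = 0.00111, adjusted p = 0.434 with an estimated correlation), and of 13 neuroectoderm genes 12 fell (camera adjusted p = 0.00132, adjusted p = 0.434 with an estimated correlation). Of 12 gap and terminal genes 11 fell and 1 rose (camera adjusted p = 0.00196, adjusted p = 0.343 with an estimated correlation), and Kr fell by 4.27.

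Further lists fell with higher adjusted p. Of 10 genes of sex determination 9 fell (camera adjusted p = 0.00333, adjusted p = 0.277 with an estimated correlation) and of 11 cellularization genes 8 fell (camera adjusted p = 0.0165, adjusted p = 0.304 with an estimated correlation). Of 14 zygotic activator and decay genes 10 fell, 11 adjusted over the list alone (camera adjusted p = 0.0206, adjusted p = 0.277 with an estimated correlation), and zld fell by 4.79. Of 11 pair-rule genes 9 fell and 1 rose (camera adjusted p = 0.0444, adjusted p = 0.617 with an estimated correlation), and eve (-0.18, adjusted p = 0.441) was not among them. Of 16 segment polarity genes 12 fell and 3 rose (camera adjusted p = 0.0394, adjusted p = 0.603 with an estimated correlation), a call that Agilent's processed signals ended at 0.0703 and Cy5 alone at 0.0524. Hsp83 (-0.29, adjusted p = 0.206) has 2 probes that went opposite ways, by 0.45 and -1.03.

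In this step 9345 genes changed, 4353 higher and 4992 lower, and 6425 by 2-fold or more. With the scan date as a block 9836 genes passed, 9278 of them among the 9345, and 8912 passed with the slide as a random block. Both 4-5 h arrays lay on a slide that held no other stage, so slide and stage cannot be told apart in this step. The share of changed genes that were higher was 46.6%, against 63.6% of 5992 without loess and 32.8% among probes above background on all 12 arrays.

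The comparison of 4-5 h with 0-1 h sums the change from the maternal supply to the embryo's own transcription. Tom rose 1241-fold, from -8.32 ± 0.71 to 1.95 ± 0.05 (SD, n = 2 per stage, adjusted p = 2.62e-09, probe on chromosome 3L from 14963310 to 14963369), CG4440 742-fold, sala 431-fold, Ama, an adhesion protein, 277-fold and Inx3, a gap junction protein, 253-fold. CG6770 fell by 7.65 on the log2 scale (probes on chromosome 2L from 12045378 to 12045581), and Gapdh2 (-7.59), dhd (-7.58), mtrm, an inhibitor of Polo (-7.28), and yin (-7.02) fell as well.

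Of 34 maternal localized and egg activation genes 32 fell, 33 adjusted over the list alone, and 1 rose (camera adjusted p = 8.83e-12, adjusted p = 0.277 with an estimated correlation), including osk (-6.67), swa (-6.20) and bcd (-5.26). Of 19 germ plasm and piRNA genes 16 fell and 1 rose (camera adjusted p = 0.000206, adjusted p = 0.383 with an estimated correlation). Of 26 neurogenic and neuroblast genes 26 rose (camera adjusted p = 1.3e-16, adjusted p = 0.277 with an estimated correlation), E(spl)mgamma-HLH 162-fold and E(spl)m5-HLH 127-fold. Of 13 neuroectoderm genes 13 rose (camera adjusted p = 9.65e-08, adjusted p = 0.277 with an estimated correlation), with l(1)sc, ac and SoxN up by 5.93, 4.51 and 3.48. Of 16 segment polarity genes 13 rose and 0 fell, 2 adjusted over the list alone (camera adjusted p = 2.5e-07, adjusted p = 0.277 with an estimated correlation), with ci up 83.5-fold, en 71.9-fold and ptc 27.9-fold, and en was above background on 1 of 2 arrays at 0-1 h. Of 8 Hox genes 8 rose (camera adjusted p = 5.44e-06, adjusted p = 0.277 with an estimated correlation), among them Ubx, which was not well above background at 0-1 h.

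Of 17 dorsal ectoderm genes 13 rose and 2 fell, 3 adjusted over the list alone (camera adjusted p = 6.1e-07, adjusted p = 0.309 with an estimated correlation). Of 19 mesoderm genes 15 rose and 3 fell (camera adjusted p = 1.63e-06, adjusted p = 0.322 with an estimated correlation), sna by 5.70 and twi by 4.25. Of 11 pair-rule genes 10 rose (camera adjusted p = 3.25e-06, adjusted p = 0.309 with an estimated correlation). Of 12 gap and terminal genes 10 rose and 2 fell (camera adjusted p = 6.14e-06, adjusted p = 0.277 with an estimated correlation), Kr by 5.66. Of 10 sex determination genes 9 rose (camera adjusted p = 0.000326, adjusted p = 0.277 with an estimated correlation) and of 7 endoderm genes 6 rose and 1 fell (camera adjusted p = 0.000819, adjusted p = 0.277 with an estimated correlation). Of 8 glia genes 5 rose (camera adjusted p = 0.00284, adjusted p = 0.277 with an estimated correlation).

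Of 11 cellularization genes 8 rose and 2 fell (camera adjusted p = 0.00593, adjusted p = 0.277 with an estimated correlation), a call lost without loess at 0.0764, and slam fell by 2.87. Of 92 ribosomal protein genes 86 rose, 87 adjusted over the list alone (camera adjusted p = 3.55e-18, adjusted p = 0.343 with an estimated correlation), with a median of 1.21 that was -0.22 without loess, where 3 rose and kept probes as a whole shifted by -0.68. RpS19b rose by 2.16. The ATP synthase and cytochrome c oxidase list rose in 17 of 28 members and fell in 3 (camera adjusted p = 0.0011, adjusted p = 0.54 with an estimated correlation), with a median of 0.57 that was -0.45 without loess, against that shift of -0.68. Of 23 muscle genes 6 rose, 5 adjusted over the list alone, and 2 fell (camera adjusted p = 0.0341, adjusted p = 0.72 with an estimated correlation), with a median of 0.43 that was -0.42 with scaling between arrays and, against the same shift, -0.07 without loess. Mhc (0.58, adjusted p = 0.0819) and eve (-0.24, adjusted p = 0.343) did not pass.

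In this comparison 7284 genes changed, 2831 higher and 4453 lower, and 4019 by 2-fold or more. With the scan date as a block 7792 genes passed, 7187 of them among the 7284, and 6665 passed with the slide as a random block. As both 4-5 h arrays lay on a slide that held no other stage, slide and stage cannot be told apart in this comparison. The share that was higher was 38.9%, against 61.7% in the authors' table.

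**Figure D2:**
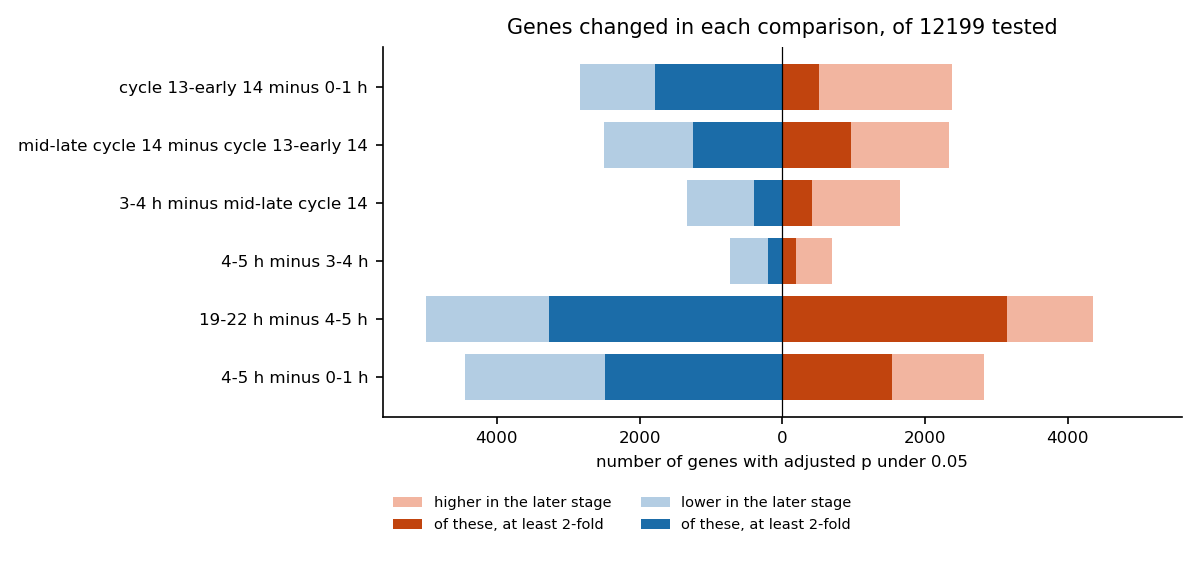
Number of genes called changed (horizontal axis) in each of the 6 comparisons (vertical axis), higher to the right and lower to the left, with genes of at least 2-fold in darker bars. The step to 19-22 h held 9345 changed genes and the step from 3-4 h to 4-5 h held 1436.

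**Figure D3:**
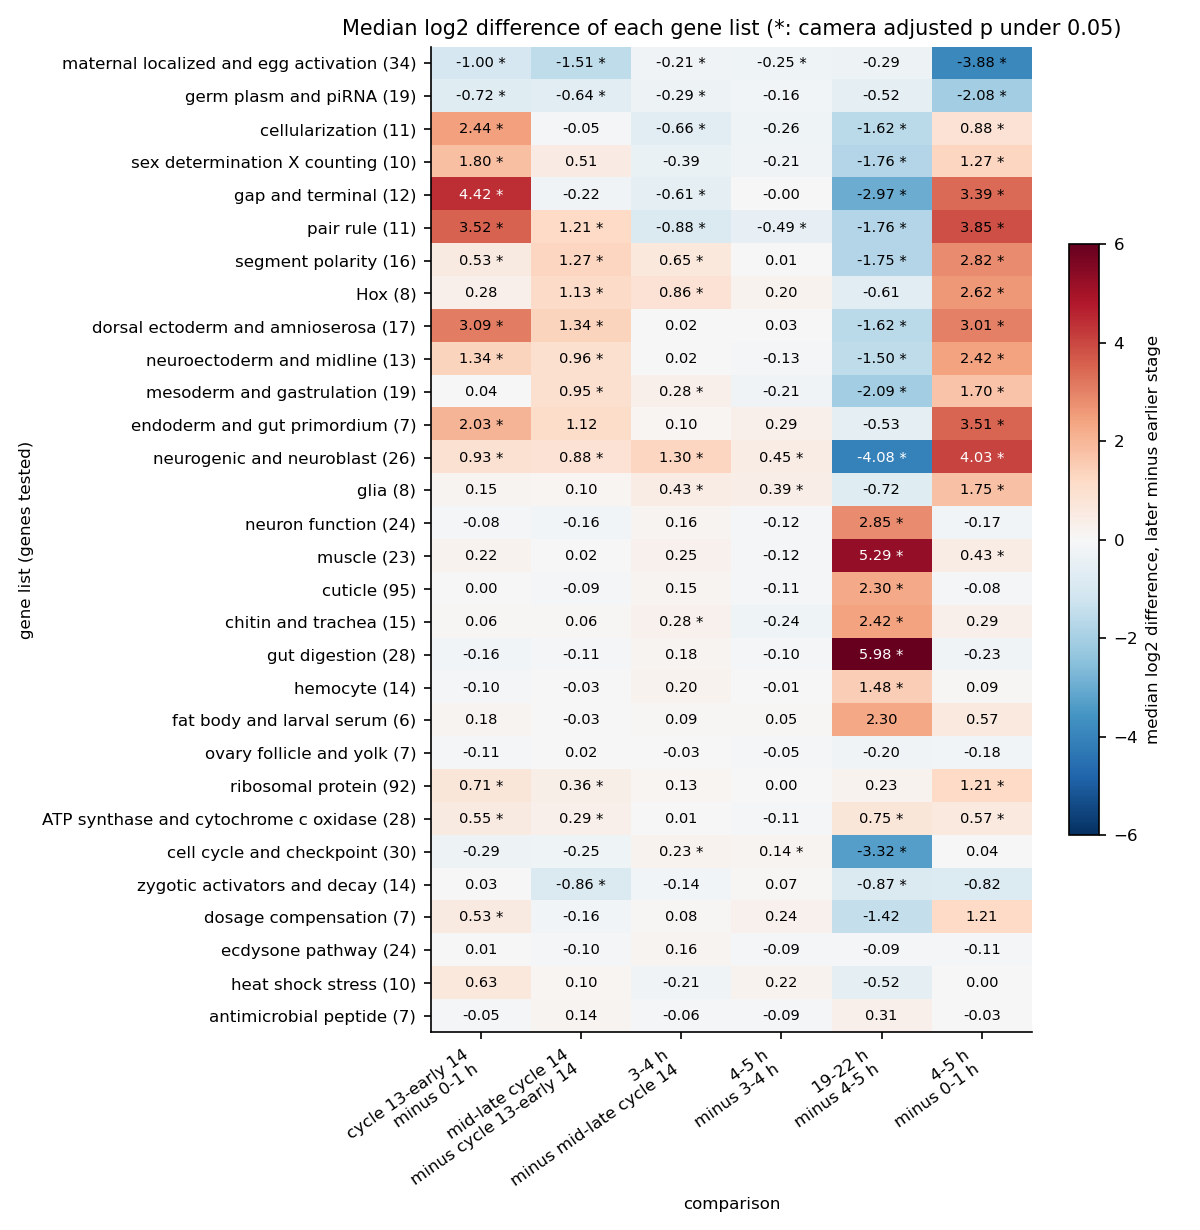
Median log2 difference, later minus earlier stage, of each gene list (vertical axis) in the 6 comparisons (horizontal axis), with a star at camera adjusted p under 0.05 at the preset correlation. The gut digestion list has 5.98 in the step to 19-22 h and the maternal list -3.88 from 0-1 h to 4-5 h, and the ribosomal protein list's 1.21 from 0-1 h to 4-5 h was -0.22 without loess, where kept probes as a whole shifted by -0.68.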

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

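The signals of the contig probes were counted after the gene results were seen, with no test of an explanation. The array holds 60025 contig probes that no comparison of genes tests. Of them 20354 (33.9%) were well above background in Cy5 on both arrays of at least 1 stage. Spots of contig probes were part of the within-array loess, so the log ratios of genes rest on them too. With loess on catalogue probes alone, 6044 genes passed from 0-1 h to cycle 13-early 14, 4423 of them among the 5212. Above background on both arrays were 7142 contig probes at 0-1 h, 12835 at cycle 13-early 14, 13186 at mid-late cycle 14, 10372 at 3-4 h, 13132 at 4-5 h and 18049 at 19-22 h, and 4201 were so at 19-22 h alone. Single arrays of repeat 1 and repeat 2 held 26790 and 16369 at mid-late cycle 14 and 29396 and 22715 at 19-22 h, with repeat 1 on the first scan date, so the counts differ by array. Of the 20354, 10715 (52.6%) differed among stages by the F test, and 4315 of these (40.3%) had their highest mean at 19-22 h. From 0-1 h to cycle 13-early 14, 3662 contig probes rose and 1883 fell, and in the step from 3-4 h to 4-5 h 27 rose and 24 fell. The contig probes carry no coordinates or gene names here, so no gene or region can be named for them.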

How the results depend on the processing

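The scan date as a block, the second scan date alone, loess on catalogue probes alone and background parameters fitted on all spots were chosen only after results were seen. Scaling to spike-ins was not run, since at most 46 spike-in spots in Cy5 and 14 in Cy3 per array were above background. The count of genes that differ among stages lay between 10713 and 11055 with each array left out in turn, and that of called lists between 72 and 83. With 1 array left the stage is assumed to vary like the others. Requiring 2-fold gave 2291, 2210, 815 and 393 genes for the 4 steps up to 4-5 h and 4019 for 4-5 h against 0-1 h. Without loess the counts were 1842, 784, 115 and 16 for these steps, 5992 for the step to 19-22 h and 4396 for 4-5 h against 0-1 h. With background parameters fitted on all spots they were 3724, 3036, 1472 and 139 for the 4 steps up to 4-5 h. They were 7438 for the step to 19-22 h and 5566 for 4-5 h against 0-1 h. The F test gave 9876 genes with background parameters fitted on all spots and 8960 without loess. For the steps to 3-4 h and 4-5 h, Agilent's processed signals gave 1857 and 803, the authors' table gave 1503 and 536, and the second date alone gave 4885 and 4521. On that date 4 stages have 1 array each and the spread comes from the repeats of 3-4 h and 4-5 h, which share slides and differ less, so counts that involve those 4 stages rest on too small a spread. For the step to 4-5 h the slide as a random block gave 667, the scan date as a block 2361 and a fit of the 2 stages alone 4521. Such a fit gave 4539, 3952 and 3229 for the steps to cycle 13-early 14, mid-late cycle 14 and 3-4 h. It gave 8956 for the step to 19-22 h and 8127 for 4-5 h against 0-1 h. The main fit shares 1 estimate of the spread over stages whose repeats differ unequally. Measured by these repeats, its p-values can be too small for stages on both scan dates and too large for the step to 4-5 h. With each array left out in turn the counts ranged from 4149 to 5714, 4071 to 5295, 1500 to 3520 and 470 to 1914 for the 4 steps up to 4-5 h, 8470 to 9373 for the step to 19-22 h and 6041 to 7793 for 4-5 h against 0-1 h. In the comparisons without 19-22 h, the highest counts came when a 19-22 h array was left out. Such an array affects those comparisons only through the shared estimate of the spread. The cause of the other changes was not tested. With the repeat number as a block the counts were 5590, 5249, 3430, 1717, 9558 and 7546.

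Of 184 called values of named genes, 54 lost their call without loess, 26 with background parameters on all spots, 18 with Agilent's processed signals and 14 in the authors' table. Aquantile ended 0 calls, which was fixed in advance, as it leaves the log ratios as they are. Where it counts among other scalings it adds no separate check. Of the values not called, 3 gained a call with the scan date as a block, those of Kr at mid-late cycle 14, gcm at 4-5 h and Hsp83 at 19-22 h. That block ended 1 named call, and the slide as a random block ended 8 and added 0. Values turned their sign in 8 cases: Mhc with scaling between arrays to -0.59 at cycle 13-early 14 against 0-1 h and to -0.58 at 4-5 h against 0-1 h, nullo with parameters on all spots to 0.17 at 3-4 h and to 0.26 at 4-5 h against 0-1 h, and osk with loess on catalogue probes to 0.20 at 19-22 h. RpL32 in 4-5 h minus 0-1 h turned to -0.0223 without loess, where kept probes as a whole shifted by -0.68, and to -0.0821 with Cy5 alone. Hsp83, whose 2 probes differ in sign, turned to 0.45 at 19-22 h with the brightest probe. The cause of the other 7 was not tested. Of 78 list calls, 56 to 78 were kept in the same direction, with 56 of 75 when probes had to be above background on all 12 arrays. The scan date as a block kept 73 of 78, and the slide as a random block kept 78. Without loess 1 list turned its direction and with scaling between arrays 1, and neither passed there. Dim probes limit what could be seen, as 8053 genes had a probe above background on all 12 arrays. Averaging the probes of a gene is a limit too. Of 3989 genes with 2 or more probes, some had probes called in opposite directions. These were 98, 95, 26 and 5 genes for the 4 steps up to 4-5 h, 129 for the step to 19-22 h and 311 for 4-5 h against 0-1 h.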

Other observations

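The tests of gene length, of scan date and slide, and of embryo age were chosen only after the result was seen, and the other 3 were set before they were run. Some lists never passed camera. In the ecdysone pathway list 8 of 24 rose and 3 fell from 0-1 h to cycle 13-early 14 (camera adjusted p = 0.179), and from 4-5 h to 19-22 h 7 rose and 9 fell (camera adjusted p = 0.882). Of 10 heat shock and stress genes 4 rose and 4 fell in the step to 19-22 h (camera adjusted p = 0.983), where the median (-0.52) and the mean (0.23) differ in sign. In the same step 5 of 6 fat body and larval serum genes rose and 1 fell (camera adjusted p = 0.142), 3 of 7 antimicrobial peptide genes rose and 1 fell (0.53), and 2 of 7 ovary follicle and yolk genes rose and 2 fell (0.791). The testis and male list had 4 tested members, too few for the list test.

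X-linked genes moved apart from autosomal genes in some steps, and not in one direction. From 0-1 h to cycle 13-early 14 the median of 1949 X-linked genes was -0.04 relative to 9788 autosomal genes, against -0.02 to 0.02 in 95% of random gene sets and -0.11 to -0.05 in other settings. In the next step it was -0.04, with -0.12 to -0.04 in other settings. From 0-1 h to 4-5 h it was -0.09, against -0.04 to 0.04 in random sets and -0.25 to -0.10 in other settings. From 3-4 h to 4-5 h it was 0.03, against -0.01 to 0.01 in random sets and 0.03 to 0.06 in other settings. The steps to 3-4 h (0.01) and to 19-22 h (-0.03) lay inside the range of random sets. A rise of X-linked genes from mid-late cycle 14 to 4-5 h might have shown dosage compensation setting in. The X minus autosome median was 0.0224 on the log2 scale, just above the range of 95% of random sets, -0.0182 to 0.0198. It stayed under a bound of 0.05 set before the test was run, and the other settings gave 0.00966 to 0.05. The shift above 0.1 that the explanation called for was not seen. The median covers all 1948 X-linked genes tested, in pooled embryos whose sex is not given. A rise in a single sex or in some genes alone, or before mid-late cycle 14, could be missed, so the test cannot decide the question.

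The early zygotic genes might be short ones. Genes that rose 2-fold at cycle 13-early 14 had a median gene span, as the scanner files give it, of 2974.5 bp (410 genes with a span of 511), and genes that first rose 2-fold at mid-late cycle 14 had 2327 bp (649 of 732), a ratio of 0.782 (two-sided permutation p = 0.0062, 100000 permutations). The hypothesis needed a ratio of 1.5 or more, and the difference went the other way, with the longer median span in the genes that rose first. The median over all 10464 tested genes with a span was 2343.5 bp. In the dimmest genes by intensity the ratio was 1.24, against 0.614 and 0.648 in the middle and brightest. As 130 of the 511 genes were below background on both arrays at 0-1 h, the rest had signal there on at least 1 array, and for genes silent at 0-1 h the question stays open.

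With background parameters fitted on all spots, the repeat 1 arrays at 3-4 h and 4-5 h deviated together from repeat 2, with r = 0.947 across genes. Bright specks in the local background may account for this, as Agilent's processed signals kept at most 33.5% of the median difference of dim genes. Embryos of another age in the repeat 1 collections would leave a difference of maternal genes in place. That difference fell from 0.91 and 0.99 to at most 0.0559 in size once outlier spots were left out of the fit. This argues against age as the source of the joint deviation. A small age difference could be missed, as the maternal list's median changed by only -0.25 from 3-4 h to 4-5 h. With Agilent's processed signals the maternal difference was -0.16 at both stages. At 3-4 h, repeat 1 correlated with the mid-late cycle 14 arrays by 0.8965 and 0.911, and repeat 2 by 0.876 and 0.8868. An age difference there stays open. The deviation r was -0.11 in the setting used here.

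The repeats of 3-4 h and 4-5 h, which share a slide, differed less than repeats of the other 4 stages, whose SD was 2.46 times as large. Scan date and slide may add to this, since repeat deviations of the 4 stages scanned on both dates correlated across genes by at least 0.233 with each other and by at most 0.0665 in size with those of the other stages. A shared slide did not set the size of this correlation. It was 0.639 for 0-1 h with cycle 13-early 14 and 0.233 for mid-late cycle 14 with 19-22 h, pairs that share slides. For 0-1 h with mid-late cycle 14, which share no slide, it was 0.585. The labels give the 19-22 h repeats as 21-22 h and 20-22 h, and a different collection window remains open: the 19-22 h deviation correlated by 0.136 across genes with the change from 4-5 h, which lies between the bounds of 0.1 and 0.3. All 4 stages scanned on both dates had repeat 1 on the first date and repeat 2 on the second. Scan date and collection therefore cannot be told apart at any of them. Other biological differences between collections were not tested.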
